A study of Mus musculus with 2 samples.

How the data were processed

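Total RNA was sequenced from the midbrain of mice of strain B6NCrl on postnatal day 0. The labels give 1 group of 2 animals, pup 1 (replicate 1) and pup 3 (replicate 2), with a single midbrain and a single library for each. Per the labels' protocols, RNA was extracted with the mirVana method, the manual of a SMARTer Ultra Low kit was linked, the size range was above 200 nt, the starting quantity was 10 ng and 2 spike-in references were named. Both animals carry the same donor identifier, and sex was not collected. The labels say that the libraries come from separate animals.

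For each library the authors deposited a gene table and a transcript table. Per the text record deposited with the tables, they were derived from alignments to the transcriptome, with build mm10 and GENCODE annotation M4. The program and its version are not given in the sources used here, although the column names are those that RSEM writes. Whether counting used the strand is not given either, so the values of a gene and of an antisense partner cannot be separated with certainty. The expected counts deposited per gene are estimates of the reads assigned to it, not whole numbers where reads were shared among genes. TPM values deposited by the authors are scaled to a fixed sum over every feature in the file, spike-ins included, after division by effective length. FPKM columns were also deposited and were not used here. The deposited transcript tables add the percent of a gene's TPM carried by each transcript. The authors' tables further hold posterior mean estimates and the bounds of a credibility interval of the posterior mean TPM, whose level is not stated. That interval need not contain the maximum-likelihood TPM.

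The gene tables held 69691 rows, of which 43346 were Ensembl genes, 26248 carried numeric identifiers, 96 were ERCC spike-ins and 1 was phiX. Symbols, biotypes and coordinates were taken from GENCODE M21, which uses the same build as mm10, by matching Ensembl identifiers without their version. A symbol was found for 42462 genes (98.0%), and genes without one held 0.154% of the counts of pup 1 and 0.162% of those of pup 3. Where a symbol had more than 1 identifier, the identifier with the highest mean count was used. Rmst, on the long noncoding RNA list, was not matched, so 8 of its 9 members were read.

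Summed expected counts were 36934868 in pup 1 and 40769103 in pup 3, spike-in and numeric rows included. Among genes at a mean of 1 TPM or more, 1 count was worth a median of 0.0195 TPM in pup 1 and 0.0179 TPM in pup 3. A count was called whole within 0.005. A count of 0 was taken to allow up to 3 counts, and intervals on counts are exact binomial intervals at 95%. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

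With 1 group there is no contrast between conditions. The values computed were each list's median TPM per library, gene pair ratios within each library, transcript shares, and the difference between the pups. Ratios were computed as log2 of TPM after adding 0.1 to each value, which understates the ratios of low genes. A pair was called apart where both libraries had the same sign, the mean exceeded 1 in size and 3 SD, and the deposited credibility intervals did not overlap in either library. An exact two-sided sign-flip test over 2 animals cannot give a p below 0.5, so no p is given. The level of a list was set beside 10000 random lists of as many protein-coding genes, drawn from all protein-coding genes in the table, as a percentile of the median. The difference between pups was taken per gene among genes at a mean expected count of 100 or more, with a threshold of 1 on the log2 scale. For lists, it was taken over members at a mean of 1 TPM or more, and set beside 10000 random lists of genes of any type, matched on mean expression in 20 bins. Bootstrap intervals of a median are 95% intervals over 1000 resamplings of its genes. Each animal has 1 library, so these differences have no replicate check and percentiles describe these libraries only.

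Correlation between the pups was computed across protein-coding genes at 1 TPM or more in both libraries, on log2 of TPM after adding 1. Expected counts were rounded to whole numbers for edgeR 4.0.16, which gave TMM scaling factors and an intercept-only dispersion, and for DESeq2 1.42.0, which gave size factors. Genes at a mean count of 10 or more entered the edgeR fits, and the DESeq2 size factors were taken over all genes. The remaining steps used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

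The difference between pups was tested on simulated data, with counts drawn at the real genes' means, library sizes and fitted dispersion, and read for 13318 genes. The threshold of 1 was passed by 67 of 67 genes changed 3-fold, by 66 of 66 changed 4-fold, by 27 of 67 changed 2-fold, and by 6 of 13118 unchanged genes. For lists of 10 genes, 100 of 100 shifted by 0.5 on the log2 scale fell outside the central 95% of random lists. So did 4 of 100 unshifted lists. Simulated genes varied independently with 1 common dispersion, so the behaviour of lists whose genes vary together was not tested. No reads were shared among simulated genes, so these rates need not hold for genes whose counts were not whole.

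The 33 gene lists, the 22 gene pairs, the 12 genes read for transcript shares, the thresholds and the rule for named genes were fixed before the data were examined. Genes named are the 10 nuclear protein-coding genes with the highest mean TPM, the 3 highest members and the lowest member of each list, all sex-linked members, both genes of each pair, the 10 genes with the largest difference between pups in each direction, and the genes read for transcript shares. Some genes and pairs that this rule selects are not reported here. Other genes named below were chosen after their values were seen. Alternatives tried were other pseudocounts, other filters, posterior means in place of maximum-likelihood values, TMM and DESeq2 scaling of counts, spike-in scaling, counts not divided by length, TPM rescaled to nuclear protein-coding genes, and each replicate left out in turn.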

Results

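The midbrain holds dopaminergic cell groups, part of the serotonergic ones, the colliculi and the tegmentum, and the series profiled its RNA on the day of birth. There were 2 libraries, 1 from each of 2 pups, with 36934868 (pup 1) and 40769103 (pup 3) expected counts. Values below are TPM as mean ± SD over the 2 pups (n = 2) unless a pup is named.

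Transcripts of the neuronal cytoskeleton led the tissue. Tuba1a, the alpha-tubulin of growing neurons (ENSMUSG00000072235.5, chromosome 15, 98949837 to 98953703, mm10), was the most abundant nuclear protein-coding gene at 15288 ± 792 TPM (SD, n = 2). It was followed by the beta-actin gene Actb at 7437 ± 105 and by Nnat, an imprinted gene of the developing brain, at 7177 ± 67.8. Next came Tmsb10, an actin-binding peptide, at 5699 ± 225 and Stmn1, a microtubule regulator, at 5376 ± 62.2. Ppia, Ftl1, Ubb and Tubb2a followed, from 4359 ± 2.65 for Ppia to 3813 ± 253 for Tubb2a. The 10 highest genes together held 6.11% ± 0.133 of TPM. For 9 of these 10 genes, all but Nnat, the counts were not whole (tolerance 0.005), as happens where reads are shared among genes or pseudogenes.

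Nuclear protein-coding genes held 83.4% ± 0.320 of TPM and the 13 mitochondrial protein-coding genes 4.76% ± 0.146. Long intergenic noncoding genes held 1.33% ± 0.226, with 1.17% in pup 1 and 1.49% in pup 3. A further 2.83% ± 0.0838 of TPM was assigned to 6 unprocessed pseudogenes of chromosome 1 between 24612407 (Gm10222) and 24616197 (Gm29216), copies of mitochondrial sequence, so single mitochondrial gene levels are uncertain. At 1 TPM or more in both pups there were 14885 genes, 13343 of them protein-coding (62.1% of the 21474 protein-coding genes in the table) and 244 lincRNA genes. Of the 14885, 1767 were at 100 TPM or more in both pups and 101 at 1000 or more.

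The pups were close to each other across genes. Over 13343 protein-coding genes, Pearson's r of log2 TPM was 0.996 and Spearman's rho was 0.995; genes are not independent replicates, so no p is given. The median absolute difference was 0.11 on the log2 scale among genes at a mean count of 100 or more, and 0.0868 at 1000 or more. The biological coefficient of variation from edgeR was 9.28% over 17846 genes. The pups were kept as 2 replicates because the labels give separate animals.

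**Figure D1:**
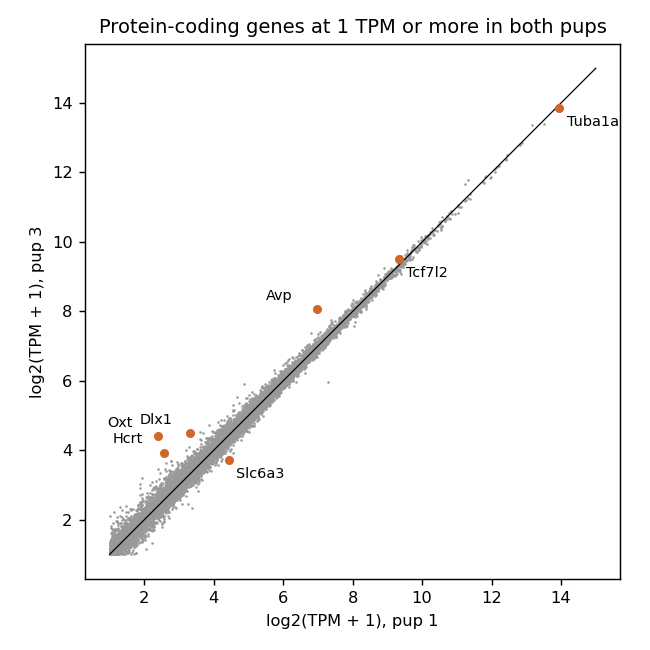
Each point is 1 of 13343 protein-coding genes at 1 TPM or more in both pups, with log2(TPM + 1) of pup 1 on the x axis and of pup 3 on the y axis, and the line marks equal values. Tuba1a and Tcf7l2 lie near the line, while Oxt, Hcrt, Avp and Dlx1 lie above it and Slc6a3 below it.

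Transcription factors of the midbrain were read at 1 TPM or more in both pups for 13 of 15 members of the list. Tcf7l2, a Wnt pathway factor of the dorsal midbrain and thalamus (ENSMUSG00000024985.14, chromosome 19, 55741820 to 55933654), was at 685 ± 57.5, far above Gata3, a factor of midbrain GABAergic neurons, at 78.1 ± 3.54, and Otx2, a forebrain and midbrain factor, at 50.7 ± 0.644. En1, a marker of the midbrain and anterior hindbrain (chromosome 1, 120602418 to 120607992), was at 8.21 ± 0.552, and the lowest member, Lmx1b, was at 0.625 ± 0.106. The median of the list was 5.71 ± 0.191, at percentile 57.0 of random lists.

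Hox genes, which pattern the hindbrain and spinal cord, were nearly unread. Of 14 members, 11 had a count of 0 in both pups, and the highest, Hoxc5, was at 0.045 ± 0.0495 on 2 counts in pup 1 and 1 in pup 3. Among forebrain patterning genes 9 of 14 were at 1 TPM or more in both pups, led by Six3 (21.9 ± 2.81), Lhx2 (19.6 ± 1.05) and Dlx1 (15.4 ± 9.04), while Tbr1, a factor of cortical projection neurons, was at 0.29 ± 0.311. The forebrain list's median was 4.39 ± 2.36, with 2.72 in pup 1 and 6.06 in pup 3. On the cerebellar granule cell list 5 of 8 genes were at 1 TPM or more, led by Barhl1 (31.5 ± 0.0707), Cbln1 (12.6 in pup 1 and 17.4 in pup 3) and Zic2 (8.85 ± 4.19). Atoh1, the factor that specifies granule cell precursors, was at 0.01 ± 0.0141 on 1 count in pup 1 and 0 in pup 3. The cerebellar list was at percentile 51.8 (44.2 in pup 1 and 58.4 in pup 3) and the forebrain list at 50.7 (34.6 in pup 1 and 60.1 in pup 3).

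Excitatory and inhibitory neuron genes were high. Slc17a6, the vesicular glutamate transporter of subcortical neurons (ENSMUSG00000030500.5, chromosome 7, 51622006 to 51671119), was at 124 ± 1.85. Slc17a7, the form used in cortex, was at 0.755 ± 0.00707, and Slc17a8, the lowest of the list, at 0.715 ± 0.106. Slc1a1 followed Slc17a6 at 41.7 ± 0.120, and the glutamatergic list was at percentile 88.5. Among GABAergic and glycinergic genes, Gad1, a GABA-synthesizing enzyme, was at 140 ± 7.10, above Gata3. Slc6a5, the glycine transporter of glycinergic neurons, was at 0.245 ± 0.0778. This list was at percentile 98.8.

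All 12 dopaminergic genes were at 1 TPM or more in both pups, with a median of 9.63 ± 0.0318 (percentile 77.2). Th, the rate-limiting enzyme of dopamine synthesis (ENSMUSG00000000214.6, chromosome 7, 142892752 to 142931128), was at 26.1 ± 5.31. Ddc, which acts after Th, was at 19.9 ± 0.269 and Aldh1a1, an enzyme of ventral dopaminergic neurons, at 17.9 ± 4.41, while Kcnj6 was lowest at 2.18 ± 0.488. The 4 serotonergic genes ran from 8.86 ± 0.587 for the transporter Slc6a4 through Tph2 (7.07 ± 0.997) and Htr1a (4.08 ± 0.290) to 1.75 ± 0.248 for Fev, at percentile 55.6. Cholinergic and motor neuron genes were lower, with a median of 1.02 ± 0.0318 (percentile 17.8). Isl1 was at 16.6 ± 7.55, Slc18a3 at 4.01 ± 0.933, Slc5a7 at 1.82 ± 0.113 and Phox2a at 0.065 ± 0.0495. Neuropeptide and calcium-binding protein genes were high, at percentile 99.6, led by the somatostatin gene Sst (585 in pup 1 and 533 in pup 3), the calretinin gene Calb2 (278 ± 38.2) and the tachykinin gene Tac1 (162 ± 11.3). Vip was lowest at 1.16 ± 0.559.

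Genes of immature neurons formed the highest nuclear list, with a median of 722 ± 17.0 and a percentile of 100. Stmn1 was followed by Gap43, a growth cone protein, at 2089 ± 66.3 and by Tubb3, a neuronal tubulin, at 1694 ± 83.8, and the lowest member, Elavl3, was at 51.4 ± 3.82. The synaptic and mature neuron list had a median of 117 ± 3.76 (percentile 100), led by Vamp2 (507 ± 5.70), Nefl (313 ± 22.4) and Syp (294 ± 19.1), with Nefh at 6.82 ± 0.332. Among radial glia and progenitor genes Fabp7, a lipid-binding protein of radial glia, was at 2373 ± 51.6, Vim at 202 ± 12.9 and Hes5 at 146 ± 9.24, while Notch1 was at 6.14 ± 0.453. That list was at percentile 85.0. In the proliferation list (percentile 70.1) Pcna was at 77.3 ± 0.0424, Cdk1 at 20.8 ± 1.05 and Birc5 at 11.2 ± 0.0566, and Mki67 was lowest at 1.12 ± 0.212.

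Astrocyte genes were well above those of myelin. The 11 astrocyte genes had a median of 77.1 ± 10.1 (percentile 100), led by Sparcl1 (332.5 in pup 1 and 267.5 in pup 3), Aldoc (226 ± 49.7) and Glul (205 ± 7.22), with S100b lowest at 7.05 ± 0.672. Oligodendrocyte precursor genes had a median of 12.8 ± 1.49 (percentile 78.0), with Olig1 at 148 ± 7.78, Ptprz1 at 78.0 ± 0.127, Pdgfra at 14.1 ± 1.75 and Cspg4 at 4.34 ± 0.658. Genes of myelinating oligodendrocytes had a median of 2.19 ± 0.0283 (percentile 33.2). Cnp was at 60.1 ± 6.51 and Mbp at 20.6 ± 0.644, while Opalin, a protein of mature myelin, was at 0.025 ± 0.0354 on 2 counts, both in pup 3.

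Non-neural cell types were present at moderate levels. Microglial genes (median 11.7 ± 0.389, percentile 79.0) included C1qb (58.2 ± 4.90) and C1qa (35.5 ± 3.43), with Tmem119 at 5.19 ± 0.283. Endothelial genes (7.80 ± 0.467, percentile 66.0) were led by the tight junction gene Cldn5 (108 ± 13.3), Esam (31.4 ± 2.14) and Kdr (10.3 ± 0.580), and Slco1a4 was at 2.03 ± 0.750. Pericyte and smooth muscle genes (median 8.05 in pup 1 and 6.94 in pup 3, percentile 62.5) included Rgs5 at 12.5 ± 0.318, Acta2 at 9.97 ± 1.87, Pdgfrb at 8.95 ± 1.10 and Abcc9 at 1.75 ± 0.191. Matrix genes of meninges and fibroblasts were higher (49.5 ± 2.57, percentile 99.4), with Igf2 at 172 ± 10.1, Col3a1 at 85.4 ± 2.14, Col1a1 at 56.6 ± 1.27 and Foxc1 at 2.58 ± 0.325. Ependymal and choroid plexus genes (3.10 ± 0.792, percentile 40.5) ran from Dynlrb2 (13.0 ± 2.07), Foxj1 (9.25 ± 1.52) and Tmem212 (4.65 ± 0.863) to Kl (0.37 ± 0.0566). Ttr, a choroid plexus transport protein named after its values were seen, had 22 counts in pup 1 and 146 in pup 3.

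Blood was visible through the adult globins Hba-a2 (998 ± 70.0), Hbb-bs (540.0 ± 14.5) and Hba-a1 (408 ± 15.2), none with whole counts. Of the embryonic globins on this list, Hbb-bh1 had a count of 0 in both pups and Hbb-y had 2 counts in pup 1 and 13 in pup 3. The erythroid median was 6.45 ± 0.283 (percentile 59.2). Of 9 muscle and pituitary genes 6 were below 1 TPM in both pups, and the median was 0.22 (percentile 6.6). Acta1 was at 16.5 ± 0.396, Pomc at 7.35 ± 1.03 and Tnnt3 at 2.08 ± 0.573, while Prl had a count of 0 in both pups.

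**Figure D2:**
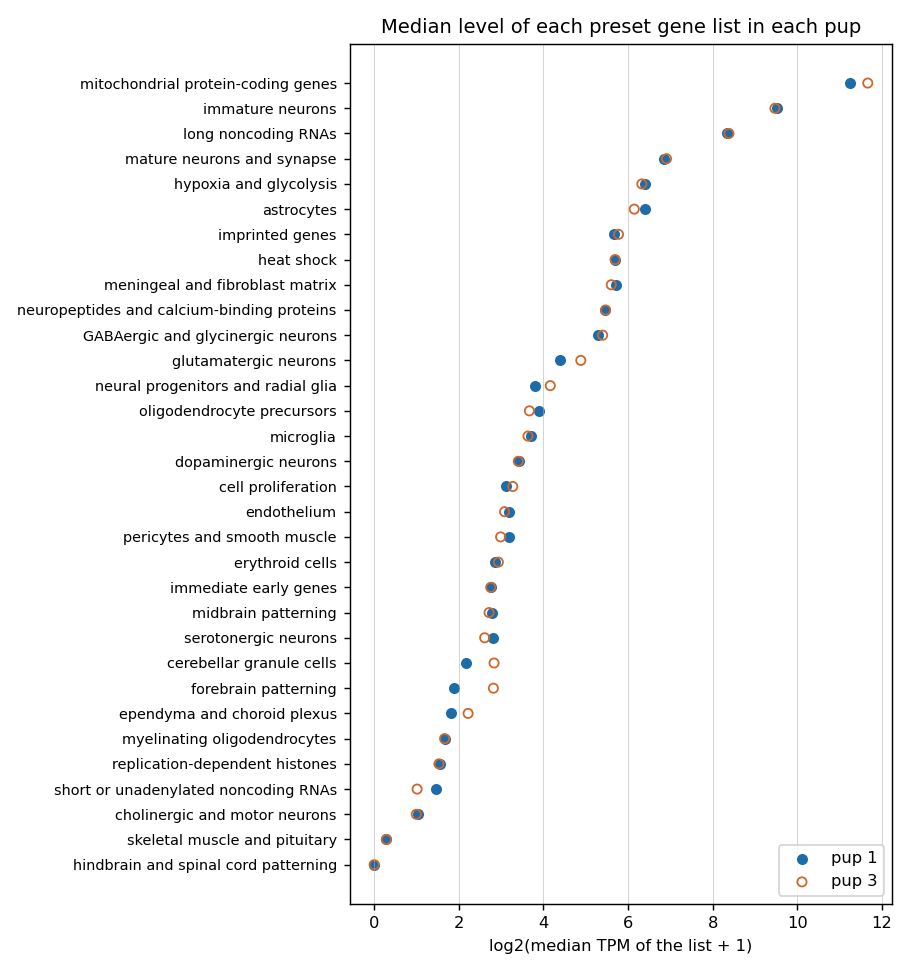
Each row is 1 preset gene list (the sex-linked list is left out) and the x axis is log2(median TPM + 1), with filled points for pup 1 and open points for pup 3. Immature neuron genes lie at 722 TPM and Hox genes at 0, and the forebrain and cerebellar lists are higher in pup 3 than in pup 1.

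Stress and activity genes were mixed. Among immediate early genes (5.77 ± 0.0283, percentile 55.3) Dusp1 was at 21.9 ± 0.325, Egr1 at 13.0 ± 2.16, Ier2 at 11.7 ± 1.14 and Fosb at 0.08 ± 0.0141. The heat shock list (50.7 ± 0.106, percentile 98.6) was led by the constitutive chaperone genes Hspa8 (2103 ± 11.8) and Hsp90aa1 (1292 ± 80.2), then Dnajb1 (74.5 ± 9.72), while the stress-induced copies Hspa1a and Hspa1b, neither with whole counts, were at 16.2 ± 0.919 and 0.535 ± 0.191. Hypoxia and glycolysis genes (81.4 ± 2.92, percentile 99.8) were led by the glycolytic enzymes Ldha (556 ± 58.6), Pfkp (350 ± 15.5) and Pgk1 (215 ± 9.41), with Vegfa, a target of hypoxia, at 1.74 ± 0.219. Mitochondrial protein-coding genes had a median of 2838 ± 588 (percentile 100), led by mt-Atp6 (11239 ± 691), mt-Atp8 (9872 ± 861) and mt-Nd1 (5345 ± 159), with mt-Nd4l at 108 ± 65.8. The 2 genes mt-Atp6 and mt-Atp8 overlap.

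Imprinted genes were high (51.8 ± 2.88, percentile 99.9). After Nnat came Ndn at 1713 ± 20.6 and Snrpn at 1044 ± 47.7, both expressed from the paternal allele, and Peg10 was lowest at 8.43 ± 1.98. Long noncoding RNAs had a median of 328 ± 7.26 (percentile 100), with Malat1, a nuclear-retained RNA, at 4473 ± 1613, Meg3 at 1491 ± 126, Snhg11 at 475 ± 69.9 and Kcnq1ot1 at 0.815 ± 0.304. Replication-dependent histones, whose mRNAs end without a poly(A) tail, had a median of 1.91 ± 0.0212 (percentile 25.2). Hist1h4d was at 54.9 ± 1.45, Hist1h2bc at 39.6 ± 5.08, Hist1h1c at 21.9 ± 0.219 and Hist1h1a at 0.04 ± 0.0566. Most genes of this list had counts that were not whole, as happens where reads are shared among genes. Short noncoding RNAs (1.39 ± 0.523, percentile 22.9) were led by Rn7sk (323 ± 13.4), Rpph1 (109 ± 5.81) and Rmrp (2.56 ± 0.488), and 2 of 8, Scarna17 and Vaultrc5, had a count of 0 in both pups. How well the library method captured short RNAs or RNAs without a poly(A) tail was not tested. The levels of the histone and short noncoding lists therefore need not be those of the tissue.

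Ratios within each library showed neonatal forms of several channel and receptor genes above their adult counterparts. Of the 19 preset pairs reported 17 were apart, 15 with the gene named first higher. Glra2, a fetal glycine receptor subunit, exceeded Glra1 by 6.51 ± 0.24 on the log2 scale (SD, n = 2), and the NMDA receptor subunit gene Grin2b exceeded Grin2a by 2.93 ± 0.35. The sodium channel gene Scn3a exceeded Scn1a by 1.06 ± 0.042. Slc12a5, the chloride exporter of maturing neurons, was already above the importer Slc12a2, with a log2 ratio of -3.72 ± 0.15 for Slc12a2 over Slc12a5. Dlg3 over Dlg4 was at -2.12 ± 0.16. Camk2b exceeded Camk2a by 3.28 ± 0.095, Nefl exceeded Nefh by 5.50 ± 0.17 and the neuronal splicing factor gene Ptbp2 exceeded Ptbp1 by 1.34 ± 0.00061.

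Among pairs of regional and cell type genes, Slc17a6 exceeded Slc17a7 by 7.19 ± 0.0095 and Slc32a1 by 3.34 ± 0.011. Otx2 exceeded Gbx2, its counterpart across the midbrain-hindbrain boundary, by 1.66 ± 0.40 (1.94 in pup 1 and 1.38 in pup 3). Tissue RNA does not show where Gbx2 was expressed, so this ratio does not measure a share of hindbrain. Since Hoxb4 had a count of 0, En1 was at least 162-fold higher than Hoxb4 in either pup, and likewise Hbb-bt was at least 801-fold higher than Hbb-bh1, both against a floor of 3 counts per library. Gad1 exceeded Gad2 by 1.82 ± 0.27, Th exceeded Tph2 by 1.86 ± 0.094, and Pdgfra exceeded Mog by 3.87 ± 0.062. Stmn2 exceeded Mki67 by 10.35 ± 0.28.

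The 2 reported pairs that were not apart were Th over Slc6a3 (0.70 ± 0.24) and Dcx over Rbfox3 (0.74 ± 0.17). Counts not divided by length turned the sign of Th over Slc6a3 to -0.26. For Dcx over Rbfox3 they gave 2.26.

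**Figure D3:**
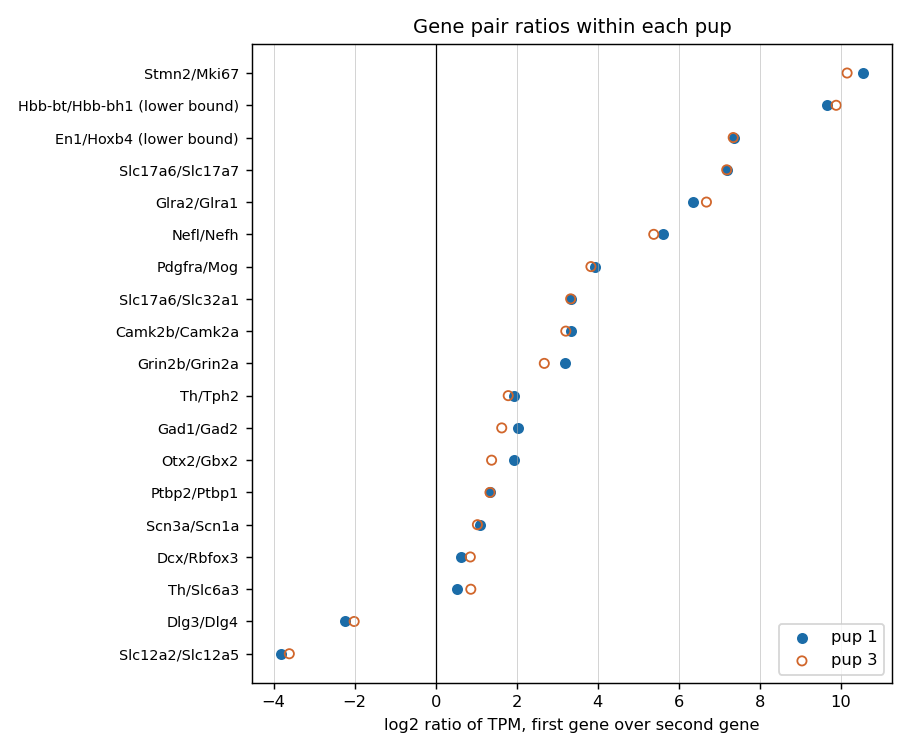
Each row is 1 of 19 gene pairs, with the log2 ratio of TPM on the x axis, filled points for pup 1 and open points for pup 3; the rows marked as lower bounds use 3 counts for the gene at 0. Glra2/Glra1 lies at a mean of 6.51 and Slc12a2/Slc12a5 at -3.72.

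The leading transcript of each of the 12 genes read was the same in both pups. Ntrk2, the receptor of BDNF, was split between a transcript whose annotated protein has 821 amino acids (56.9% ± 0.502 of the gene's TPM) and one of 476 amino acids (43.1% ± 0.502). Map2 was led by a transcript of 467 amino acids (36.0% ± 2.68), ahead of one of 1828 amino acids (20.8% ± 0.354). The leading transcripts held 47.8% ± 0.396 of Mapt (390 amino acids), 56.8% ± 3.02 of Mbp (195), 93.3% ± 0.686 of Snap25 (ENSMUST00000028727.6) and 67.0% ± 1.61 of Cdc42 (ENSMUST00000030417.9).

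For Gad1 the leading transcript (ENSMUST00000140478.1, 52.8% ± 0.636) is annotated as noncoding, ahead of the coding transcript of 593 amino acids (39.5% ± 2.75). In Ank3 a transcript of 1961 amino acids held 27.5% ± 2.52 against 24.2% ± 0.438 for one of 459 amino acids, a gap of 4.78 percentage points in pup 1 and 1.84 in pup 3. Th was read from 1 transcript alone (100%), and App had 1 transcript in the file.

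Sex was not collected, and the sex-linked genes differed between the pups. Ddx3y, Eif2s3y, Kdm5d and Uty, all on the Y chromosome, had 2618, 2032, 619 and 568 counts in pup 1 and 0 in pup 3. On TPM, pup 1 was at least 719.6-fold higher for Ddx3y, at least 635.5-fold for Eif2s3y, at least 242-fold for Kdm5d and at least 192.5-fold for Uty, against a floor of 3 counts. Xist, the noncoding RNA of the inactive X (ENSMUSG00000086503.3, X chromosome, 103460366 to 103483254), had 2.26 counts in pup 1 and 10434 in pup 3. Scaled to equal depth that is a log2 ratio of 12.03 (exact 95% interval 10.35 to 15.25). Tsix, which lies on the other strand of the same region, had 14.2 counts in pup 1 and 3120 in pup 3, and its reads cannot be told from those of Xist where counting does not use strand. For this list a mean has no use, and its median was 7.96 TPM in pup 1 and 0 in pup 3, with a percentile of 79.3 for the means.

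Beyond the sex-linked genes, and among protein-coding genes at a mean count of 100 or more, hypothalamic peptide genes and forebrain factors had the largest differences towards pup 3. Ttr, which lay below that filter, was higher by 2.47. Oxt, the oxytocin gene (chromosome 2, 130576173 to 130577054), was at 4.28 TPM in pup 1 and 20.4 in pup 3, a log2 difference of 2.23. Six6, an eye and hypothalamus factor, was higher by 1.59, Hcrt, the orexin gene, by 1.53 and Dlx2, a forebrain factor, by 1.41. The noncoding or unnamed genes among the 10 highest were Xist, Tsix, ENSMUSG00000103565.1 (0 counts in pup 1 and 211 in pup 3, not whole) and the processed pseudogenes Gm15459 (2.46), Gm9493 (1.70) and Gm6136 (1.48), whose reads were shared with other genes. Below the Y-linked genes, the largest differences in the other direction were those of Gm15429 (-1.50), G530011O06Rik (-1.50), mt-Nd4l (-1.32), Gm17122 (-1.32), Gm42416 (-1.30) and Mtbp (-1.20), none with whole counts in both pups. Between the pups the deposited intervals overlapped for ENSMUSG00000103565.1, Gm15459, mt-Nd4l, Gm42416 and Mtbp, so a difference in these genes is uncertain. For Mtbp the log2 difference was -0.38 with TMM-scaled counts.

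In all, 42 of 13318 genes (0.315%) differed by more than 1 on the log2 scale, 29 higher and 13 lower in pup 3. Of the 42 genes, 13 had whole counts in both pups and 8 were on the X or Y chromosome. With TMM-scaled counts there were 36 such genes, 25 higher and 11 lower, and 33 genes passed on both scales. With a mean count of 20 or more in place of 100 the number was 199, without a filter 2351, and with a pseudocount of 1 it was 27. Scaling to the spike-ins put the median log2 difference of all genes at -0.436. The differences given here are relative to the bulk of genes.

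Of 31 gene lists compared between the pups (sex-linked list left out), 3 lay above the central 95% of matched random lists and 5 below. By chance 1.6 in all would lie outside if lists, and the genes within them, were independent. Forebrain patterning genes were higher in pup 3 for 7 of 9 members, with a median log2 difference of 0.56 (percentile 100), including Dlx1 at 1.27 and Six3 at 0.26, while Lhx2 was at -0.11. The 5 of 8 cerebellar list members compared were all higher in pup 3, with a median of 0.57 (percentile 99.9). They ran from Barhl1 at 0.0046 to Zic2 at 0.99, and with TMM-scaled counts Barhl1 was at -0.13. The 3 members below 1 TPM in both pups were lower in pup 3, on few counts. Atoh1 was at -0.26 (1 count in pup 1 and 0 in pup 3), Gabra6 at -0.55 (4 and 1) and Cbln3 at -0.28 (28 and 29). The 7 long noncoding RNAs compared had a median of 0.30 (percentile 100) and none was lower in pup 3, from Rian at 0.0015 and Gas5 at 0.082 (0.0030 with TMM-scaled counts), both nearly equal in the pups, to Malat1 at 0.75.

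Lower in pup 3 were 9 of 11 astrocyte genes (median -0.19, percentile 0; with TMM-scaled counts Slc1a3 also lay below 0, at -0.057), with Aldoc at -0.45 and Sparcl1 at -0.31, and 6 of 7 oligodendrocyte precursor genes (median -0.25, percentile 0), where Ptprz1 was at 0.0033 and at -0.021 with TMM-scaled counts. Dopaminergic genes were lower for 8 of 12 members (median -0.16, percentile 0.2), with Slc6a3, the dopamine transporter gene, at -0.76, Aldh1a1 at -0.51 and Th at -0.42, and Kcnj6 at 0.44. Endothelial genes (8 of 9, median -0.14, percentile 1.1) and the neuropeptide list (7 of 12, median -0.11, percentile 0.5) also lay below, although Slco1a4 was at 0.73 (0.066 with TMM-scaled counts) in the former, and Vip at 0.94 (25 counts in pup 1 and 56 in pup 3) and Calb2 at 0.28 in the latter. The remaining lists lay inside the central 95%, and the midbrain patterning list was at -0.067 (percentile 5.8).

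**Figure D4:**
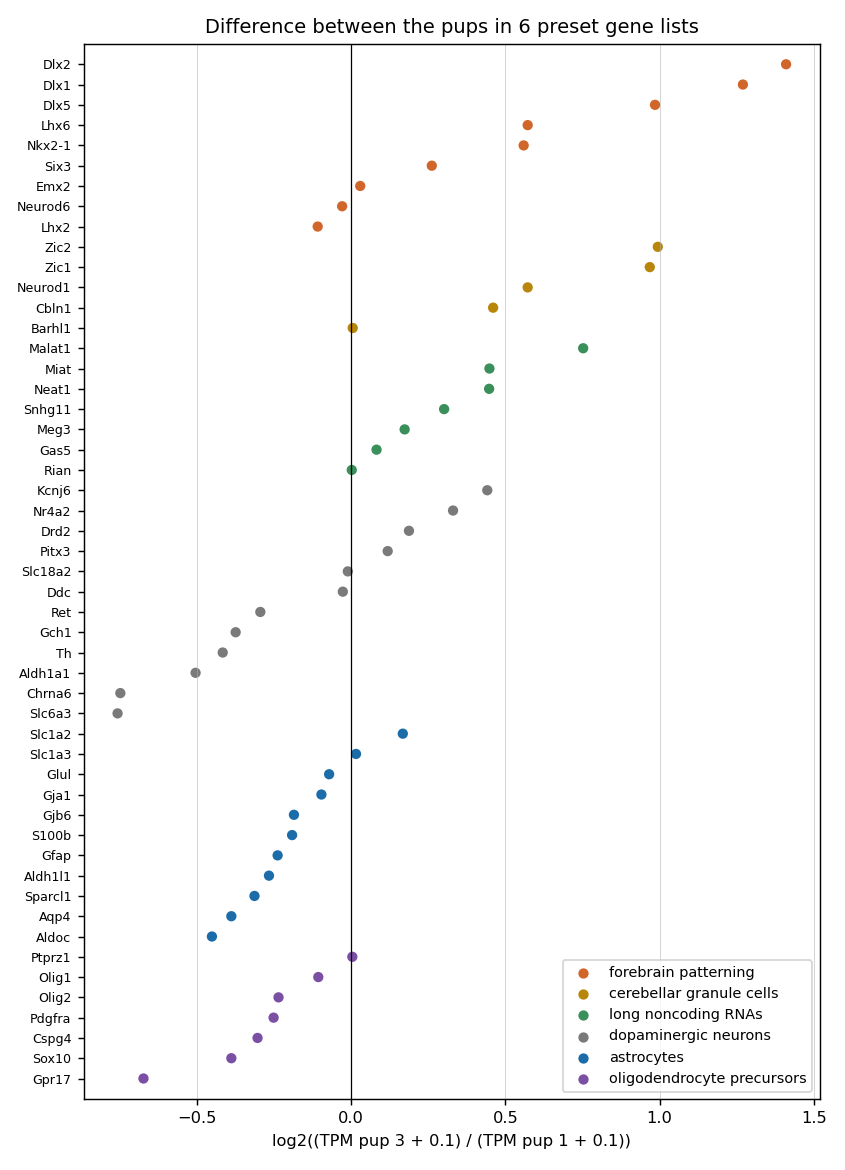
Each point is a gene of 1 of 6 preset lists at a mean of 1 TPM or more, with log2 of TPM in pup 3 over pup 1 (0.1 added to each) on the x axis and a colour for each list. Dlx2 (1.41) and Dlx1 (1.27) are highest, and Slc6a3 (-0.76) is lowest.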

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

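The test on effective length or scaling was chosen only after the result was seen. The 3 patterns below were themselves first noticed in these data. Counts in features outside the main measurement exceeded the 3 counts that a count of 0 allows in both libraries. The ERCC spike-in rows summed to 228 counts in pup 1 and 340 in pup 3, a share of 6.17 ppm of the counts (exact 95% interval 5.40 to 7.03) against 8.34 ppm (7.48 to 9.27). Rows with numeric identifiers, which no source used here names, summed to 8.93 counts in pup 1 and 13.32 in pup 3.

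The Y-linked genes were read only in pup 1 and Xist almost only in pup 3. The Y-linked sum was 5837 counts in pup 1 and 0 in pup 3. No technical explanation was tested on values apart from these counts. A difference in chromosomal sex is a candidate explanation: 4 X-linked genes known to escape inactivation, Kdm6a, Kdm5c, Eif2s3x and Ddx3x, had a median log2 difference of 0.569 towards pup 3 (range 0.437 to 0.769), while 460 other X-linked protein-coding genes had a median of 0.062. Xist in pup 1 was at 0.0239% of its level in pup 3. The labels do not record sex, but these values argue against the same chromosomal sex in both pups. Every other difference between the pups cannot be told apart from a difference in sex.

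Hypothalamic neuropeptide genes and forebrain factors were higher in pup 3, as seen in Avp, Oxt, Hcrt, Pmch, Six6, Dlx1, Dlx2, Dlx5 and Isl1. All 9 were read in pup 1 as well, from Six6 at 1.02 TPM to Pmch at 28.4 and Avp at 123.9. Whether the levels reported for either pup are those of midbrain tissue alone was not tested. TMM-scaled counts are not divided by effective length. With them a share of 1.0 of these 9 genes stayed beyond 0.5 on the log2 scale (range 0.956 to 2.13). This argues against effective length as the source of the difference in these 9 genes. Scaling was hardly tested, since the genes were chosen for a high difference and the TMM factors were 0.997 (pup 1) and 1.003 (pup 3). A larger share of hypothalamic tissue in the dissection of pup 3 may account for the pattern: of 20 further hypothalamic genes, on no preset list, 15 were at a mean of 1 TPM or more in these libraries and 12 of these were higher in pup 3, with a median of 0.698 (bootstrap interval 0.131 to 0.87) at percentile 100 of matched lists, Gal (27.0 TPM) and Foxb1 (14.9) being the most abundant and at -0.0441 and -0.168. The largest contrary value was that of Crh, at -0.748 (74 counts in pup 1 and 47 in pup 3). For 12 telencephalic genes the median of 0.137 (-0.0393 to 0.343) lay at percentile 91.95, so a telencephalic share stays open, and the most abundant, Bcl11a (70.7 TPM) and Nrgn (68.9), were at -0.0797 and -0.0153. A difference between the animals themselves was not tested.

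Long noncoding RNAs as a list were higher in pup 3, with a median of 0.301 over 7 genes (bootstrap interval 0.0819 to 0.448). Removing the trend with transcript length across protein-coding genes left a median of 0.253 (0.0958 to 0.361), and removing that with GC content left 0.247 (0.0182 to 0.489), which argues against either trend as the whole cause. A larger share of unspliced or intron-retaining RNA in pup 3 was a further candidate. Over 5101 protein-coding genes with retained-intron transcripts, their share of the gene changed by a median of 0.78 percentage points (0.71 to 0.88) towards pup 3. It was up for 3443 genes and down for 1646. These values cover protein-coding genes only, so they cannot decide whether intron retention bears on the 7 noncoding RNAs. No biological explanation was tested, since both pups belong to 1 group.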

How the results depend on the processing

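No alternative was added later. No paired analysis was possible because there is 1 group. Each value is from 2 animals, leaving 1 out leaves no spread, and the cause of a shift was not tested unless stated. The number of genes detected ranged from 14885 to 18316. Nuclear protein-coding genes held 93.4% of expected counts against 83.4% of TPM. Pearson's r was 0.99588 as reported, 0.99503 with a pseudocount of 0.1, 0.99747 without a filter, 0.99622 with TMM or DESeq2 scaling and 0.9962 with posterior means.

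Genes beyond 1 between pups numbered 199 at a mean count of 20, 2351 without a filter and 27 with a pseudocount of 1. The number was 36 with TMM or DESeq2 scaling, 31 with posterior means and 51 with spike-in scaling. Spike-in scaling put the median log2 difference of all genes at -0.436. More genes enter under the lower filters, and their counts are low. None of the 8 lists outside the central 95% changed the sign of its median under the 4 alternatives run on lists, although their percentiles were not recomputed. Among the 20 named genes Mtbp fell under the threshold in all 4 (-0.38 with TMM) and Gm42416 with a pseudocount of 1.

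Of the 19 pairs reported, counts not divided by length reversed Th/Slc6a3 (-0.26) and put Dcx/Rbfox3 apart (2.26), since gene lengths no longer enter. No reported pair changed its call with a pseudocount of 1 (run on the 17 pairs without lower bounds), with posterior means or with 1 pup left out.

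List percentiles moved by more than their spread as follows. Posterior means gave 15.5 for cholinergic, 98.3 for GABAergic, 71.4 for proliferation, 31.6 for myelinating, 60.4 for erythroid, 7.3 for muscle and pituitary, 98.8 for heat shock and 23.2 for histone genes. Rescaling to nuclear protein-coding genes gave 98.3 for GABAergic, 7.1 for muscle and pituitary and 56.2 for immediate early genes. With 1 replicate left out the ranges were 73.8 to 75.0 for dopaminergic, 52.0 to 56.6 for serotonergic, 98.2 to 98.6 for GABAergic, 99.2 to 99.5 for matrix, 57.9 to 59.2 for erythroid, 8.0 to 8.5 for muscle and pituitary, 56.4 to 57.2 for immediate early, 98.7 to 98.8 for heat shock, 23.7 to 25.6 for histone and 0 to 66.4 for sex-linked genes. The sex-linked percentile rests on pup 1. Moves within the spread between pups could be larger, from 34.6 to 60.1 for forebrain and 44.2 to 58.4 for cerebellar genes. With posterior means the leading share moved for 2 of 12 genes, Map2 (32.5%) and Th (94.3%).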

Other observations

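Receptor and channel families, chosen after the data were seen, differed in the RNA levels of their subunit genes. Among AMPA receptor subunits, Gria2, which limits calcium entry, was at 170 ± 9.24 TPM (SD, n = 2), or 64.9% of the family, ahead of Gria1 (48.3 ± 5.86), Gria4 (28.1 ± 3.30) and Gria3 (15.4 ± 1.83). Of NMDA receptor subunits, the obligatory Grin1 was at 61.2 ± 0.184 and was followed by Grin3a (32.2 ± 2.94), a subunit of young synapses, and Grin2b (27.5 ± 2.52), while Grin2c was at 0.57 ± 0.0990. Among alpha subunits of the GABA-A receptor, Gabra5 was at 71.1 ± 1.51, Gabra2 at 49.9 ± 8.48 and Gabra3 at 44.2 ± 4.24, while Gabra6, a cerebellar subunit, was at 0.06 ± 0.0424. The delta subunit gene Gabrd was at 0.305 ± 0.00707.

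Glycine receptor genes were Glrb (55.6 ± 3.88) and Glra2 (44.2 ± 5.49), with Glra3 at 2.41 in pup 1 and 2.59 in pup 3. Among nicotinic receptor genes Chrna4 was highest (37.5 ± 2.27), with Chrna3 (18.2 ± 0.325) and Chrnb2 (17.7 ± 0.573) next and Chrna6, a subunit of dopaminergic neurons, at 3.68 ± 1.36. Sodium channel genes were led by Scn2a (46.8 ± 0.884) and Scn3a (42.2 ± 2.55), with Scn8a, which rises later in development, at 9.38 ± 2.33.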
